A study of Rhagoletis pomonella with 50 samples.

How the data were processed

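The material was the central nervous system (CNS) of diapausing pupae of the fly Rhagoletis pomonella, taken from pupae that had fed as larvae on apple or on hawthorn fruit. Per the labels, each of the 50 libraries was made from a pool of 10 CNS, with 5 pools for each of the 2 hosts at 2, 3, 4, 5 and 6 months. The title of a hawthorn library of 6 months has the letter B after its replicate number. It was taken as replicate 3, and whether it is a repeat library of a pool is not stated. Fruit came from a single Illinois locality. Larvae pupated for 10 days at 24 °C under a 14:10 h light cycle, and pupae were then held at 3.5 °C and 95% relative humidity. Stranded mRNA libraries were sequenced as 100 bp single-end reads.

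Per the submitters' processing notes, cleaned reads were mapped with STAR to the genome of a related species, R. zephyria, and counted with RSEM. The versions of these tools, the read cleaning, the genome build and the annotation are not given in the sources used here. RSEM divides reads that fit several genes among them by their estimated abundance, so features with near-identical copies are uncertain. The deposited values used for all tests were expected counts per feature (estimated read counts that need not be whole), as named in the file headers. Between 13.4% and 20.9% of the features in a library had a value that was not whole. The deposited TPM values, made by the authors with RSEM, were read only to check that they summed to 1000000 in each library. The deposited transcript length, in bp and averaged over the isoforms of a feature, was used to describe features and libraries.

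Each file listed the same 29399 features. Features carry an identifier made of the word gene and a number, and the files do not pair these with names. None (0) of the 29399 identifiers matched the reference table of R. pomonella genes, which was built on another assembly. The 25 gene lists fixed before the data were examined therefore had 0 members matched, and the planned list tests (limma's camera and fry) were not run. No feature is given a gene name or a position.

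Expected counts were rounded to whole numbers, which moved no library total by more than 0.000438%. Features were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total 15) on the 10 groups of host and month, which left 13862 features with 99.9% of the counts. Libraries were scaled by TMM (trimmed mean of M values). A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 50 libraries, with robust dispersion and robust quasi-likelihood estimates in the form used before edgeR 4. P-values were adjusted by the Benjamini-Hochberg method and features with an adjusted p under 0.05 were called. All adjusted p-values of features come from this test unless another is named. Fold changes are on the log2 scale, with the standard error (SE) derived from the fold change and the F statistic. CPM values are counts per 1000000 of the TMM-scaled library total. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

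The comparisons were apple minus hawthorn at each month and averaged over the 5 months, 3, 4, 5 and 6 months against 2 months within each host, any change over the months within each host (F test), any host-by-month interaction (F test), and the host difference in the change from 2 to 6 months. Within a host, the comparisons against 2 months share their 2-month libraries and are not independent. No overlap between them is therefore reported. The rule for named features, also fixed in advance, falls back on at most 2 identifiers higher and 2 lower per comparison where names are missing. These are the called features with the largest fold change among those with a mean log2 CPM of at least 1. For comparisons of 5 libraries with 5, the values of the 2 groups had also not to overlap, and for the mean host difference its sign had to be the same at all 5 months.

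Totals of expected counts ranged from 8718271 to 30540959 per library, with a median of 14615586. On simulated counts with 100 features changed 1.5-fold and 100 changed 2-fold, the mean host comparison recovered 95 and 99 of them, and 59 and 89 with lane as a term. The apple change from 2 to 6 months recovered 28 and 71, and the hawthorn change recovered 29 and 76, or 19 and 69 with lane as a term. The changed features were drawn from those with higher mean counts, and no lane effect, length trend or outlying library was simulated. Recovery in the real data may therefore be lower. A comparison of 5 libraries against 5 thus detects few changes of 1.5-fold.

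Lanes and index types were read from the run information the authors left in the deposited data. The libraries were spread over 6 lanes. Lanes were shared unevenly among groups, and only at 6 months did both hosts have libraries in the same lane (4 apple and 3 hawthorn libraries in lane 7). Replicates 3, 4 and 5 of both hosts at 6 months carried a single index and the other libraries a dual index. Replicate pools are separate samples per the labels, and no pair of replicates agreed within sampling noise: the smallest chi-square per degree of freedom over 100 replicate pairs was 10.4. For each library, the length slope was computed as the slope of its log2 CPM deviation from the mean of all libraries on the log2 transcript length of the features. Principal components were taken from log2 CPM with a prior count of 2. Single values were compared by two-sided exact permutation tests, and correlations by 100000 permutations.

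The alternatives fixed in advance were DESeq2 size factors, no low-count filter (all features with at least 1 count), edgeR 4's bias-adjusted deviances, DESeq2 as the tool, an adjusted p under 0.01, a fit with only the 2 groups compared, the replicate number as a block, the lane as an additive term, a fit within lane 7, leaving out the 6 single-index libraries, and leaving out each library in turn. The alternatives added after seeing the data were leaving out 2 outlying hawthorn libraries, a length slope term, and fits of hawthorn months within lanes 1 and 7. As checks, host labels were permuted within each month and month labels within each host, in 100 splits each with the real one included, and lanes were shuffled within groups 100 times.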

Results

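Rhagoletis pomonella, the apple maggot fly, has a native population on hawthorn and a derived one on apple, and both pass the winter as pupae in diapause. RNA of the pupal central nervous system (CNS) was sequenced at 2, 3, 4, 5 and 6 months in the cold, from 5 pools of 10 CNS per host and month (50 libraries, 10 groups). Expected counts summed to between 8718271 and 30540959 per library. Group means ran from 12545261 ± 3117483 (SD, n = 5) in hawthorn at 4 months to 21688140 ± 7134397 in apple at 2 months. Of 29399 features, 21048 had an expected count of at least 1 in some library, and 13862 passed the count filter. The most abundant feature, gene2504, took 8.02% of all counts. Its share lay between 6.48 ± 2.23% in hawthorn at 4 months and 9.52 ± 0.974% in apple at 3 months, and it was called neither between hosts (adjusted p = 0.554) nor from 2 to 6 months (0.911 in apple, 0.838 in hawthorn). The second, gene23257, had 2.09% and the third, gene2503, had 2.02%.

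The first principal component (15.2% of the variance) followed the length slope of the libraries, a measure of how far longer transcripts were over- or under-represented. Over the 50 libraries Pearson's r was 0.938 and Spearman's rho 0.939, each with a permutation p of 1e-05, the smallest that 100000 permutations give, and the same value after adjustment over 8 relations. Without the 2 libraries farthest from the median slope r was 0.919 and rho 0.931, and within apple and hawthorn r was 0.890 and 0.955. Those 2 libraries, hawthorn replicates 2 and 4 at 4 months, lay at -93.1 and -112 on the first component, while the lowest of the other 48 lay at -31.9. Their TMM factors were 0.651 and 0.728. Both components differed between 2 and 6 months. The first rose by 23.6 in apple (exact permutation p = 0.00794, adjusted p = 0.0106 over 4 tests) and by 40.3 in hawthorn (p = 0.0159, adjusted p = 0.0159). The second (11.4%) fell from 36.9 ± 9.03 to -13.6 ± 9.05 in apple and from 22 ± 9.91 to -28.4 ± 4.41 in hawthorn (n = 5 each, exact permutation p = 0.00794, the smallest that 5 against 5 libraries allow, and adjusted p = 0.0106 in both). In hawthorn it was -26.8 ± 23.6 at 4 months and -17.75 ± 2.95 at 5 months. The low mean at 4 months rested on replicates 2 and 4, at -55.7 and -49.5. The other libraries of that group lay between -11.0 and -7.62.

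**Figure D1:**
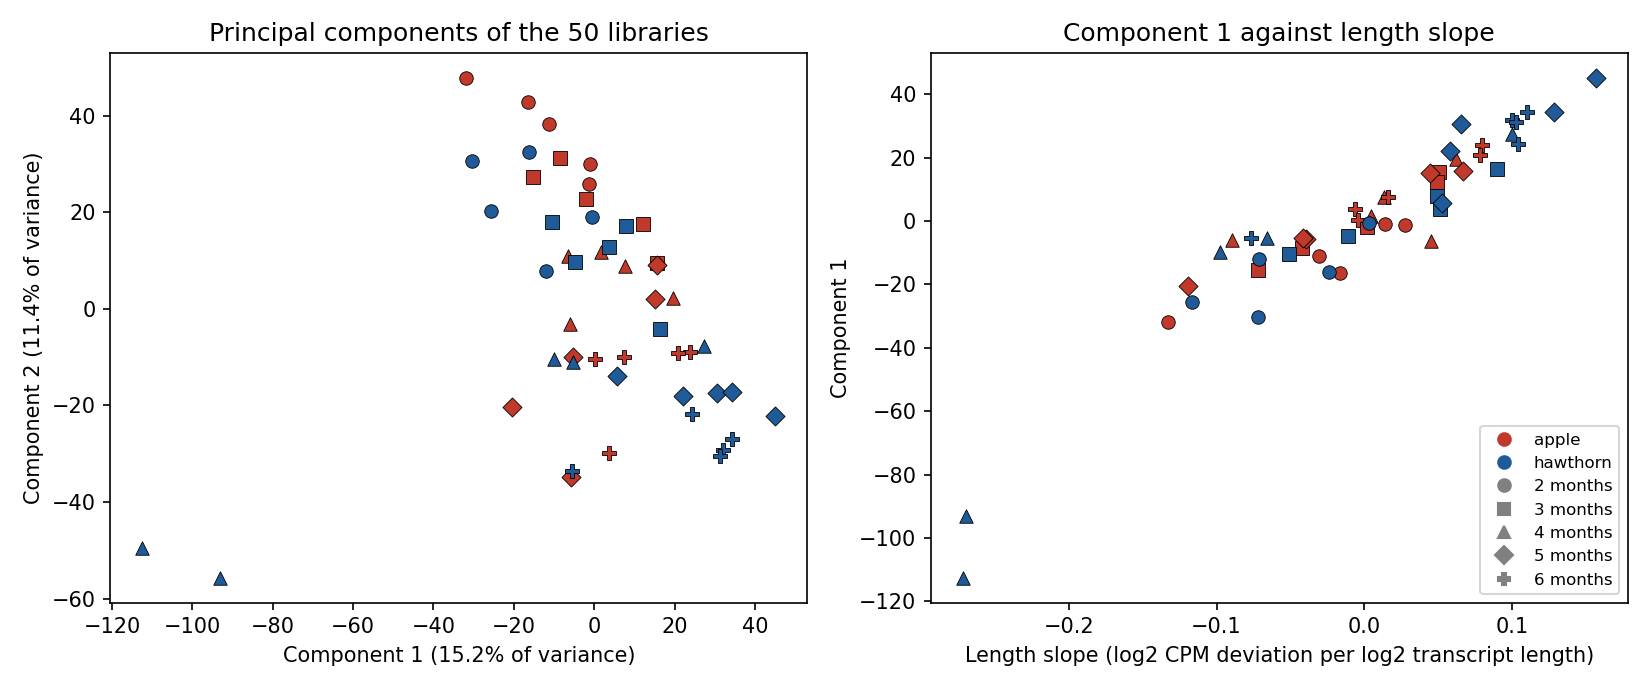
Left, first against second principal component of log2 CPM for the 50 libraries, with the share of variance on each axis. Right, first component against the length slope (log2 CPM deviation per log2 transcript length). Colour gives the host and symbol the month; 2 hawthorn libraries of 4 months lie apart at a first component of -93.1 and -112, and the second component falls from 2 to 6 months in both hosts.

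The first question was how the CNS of apple and hawthorn pupae differed across diapause. Averaged over the 5 months, 2673 of 13862 features (19.3%) differed between hosts, 1354 higher in apple and 1319 higher in hawthorn. The differences were small: the median absolute log2 fold change of the called features was 0.35, and 70 of them differed at least 2-fold. The sign was the same at all 5 months in 1437 of the 2673. The clearest single feature was gene19551, with 7.45 ± 4.03 CPM in apple and 1.59 ± 1.03 CPM in hawthorn (SD, n = 25 each), a log2 fold change of 2.27 (SE 0.225, adjusted p = 6.06e-09). It was higher in apple at each month, from 4.75 ± 2.34 against 2.01 ± 1.61 CPM at 4 months to 7.81 ± 2.66 against 0.989 ± 0.645 CPM at 6 months. Next was gene3834, at 7.46 ± 5.54 against 2.35 ± 2.13 CPM (log2 fold change 1.73, SE 0.303, adjusted p = 0.000111). On the hawthorn side, gene17606 had 1.66 ± 1.002 CPM in apple and 4.39 ± 3.30 CPM in hawthorn (log2 fold change -1.30, SE 0.252, adjusted p = 0.000338). The fourth, gene14752, had 4.14 ± 7.55 against 12.6 ± 23.1 CPM (-1.62, SE 0.439, adjusted p = 0.00771), on a few libraries far above the rest, and lost its call without the 2 outlying hawthorn libraries (adjusted p = 0.0519).

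**Figure D2:**
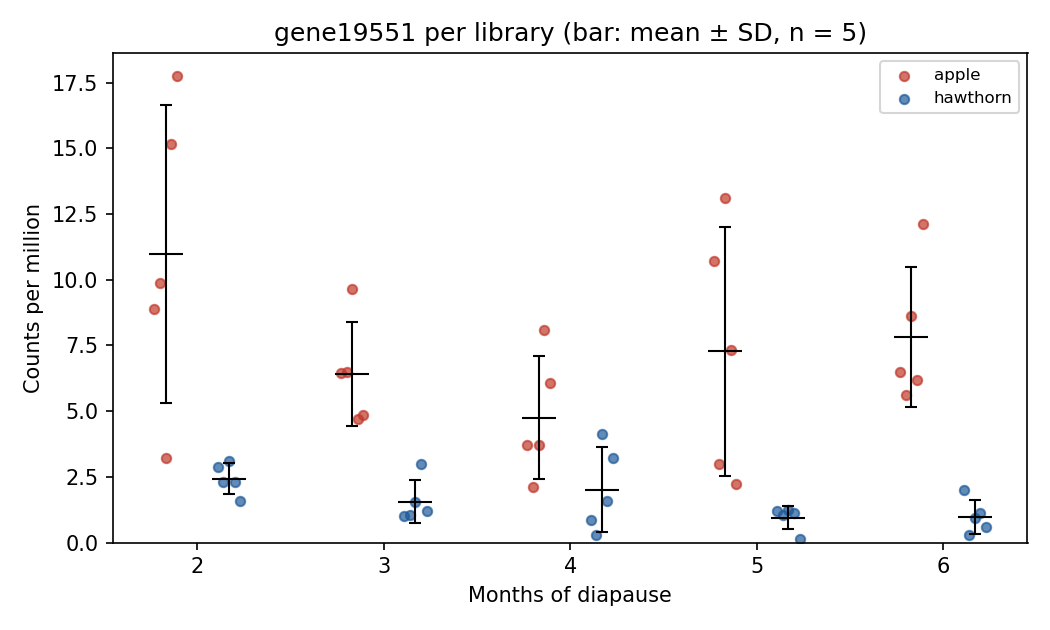
CPM of gene19551 in each library (points) by month of diapause, with the mean and SD of the 5 libraries of each host and month. Apple libraries averaged 7.45 CPM and hawthorn libraries 1.59 CPM, and at 6 months the lowest apple library (5.62 CPM) lay above the highest hawthorn library (1.99 CPM).

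Hosts and lanes overlapped only in part, and with lane as a term 21 features differed in the mean host comparison, 20 of them among the 2673. The median log2 fold change of the 2673, signed by its original direction, went from 0.35 to 0.31 and 99.5% kept their sign, while the median SE rose from 0.0932 to 0.167. Under that fit gene19551 kept its call (log2 fold change 2.17, adjusted p = 0.0128), whereas gene3834 (1.84, 0.163), gene17606 (-0.70, 0.562) and gene14752 (-0.68, 0.850) did not. Without the 6 single-index libraries 1399 features were called.

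Month by month, the hosts differed in 436 features at 2 months (233 higher in apple, 203 lower), 0 at 3 months, 1310 at 4 months (467 and 843), 894 at 5 months (402 and 492) and 75 at 6 months (55 and 20). At 3 months, where edgeR called 0 features, 1274 had an unadjusted p under 0.05 and DESeq2 called 35. At 2 months, gene19551 (10.98 ± 5.68 CPM in apple, 2.44 ± 0.588 in hawthorn, n = 5, adjusted p = 0.0103) and gene13883 (4.64 ± 1.54 against 1.56 ± 0.345, adjusted p = 0.00609) were higher in apple. Higher in hawthorn were gene17606 (8.65 ± 2.77 against 1.45 ± 0.338 CPM in apple, adjusted p = 0.00876) and gene19494 (9.60 ± 3.85 against 1.77 ± 0.537, adjusted p = 0.00254). The 2-month count lay between 98 (without apple replicate 4) and 632 (without apple replicate 2) when 1 library was left out, and was 1196 without the 2 outlying hawthorn libraries, 1079 with the length slope term, 1080 when only the 2 groups were fitted and 780 by DESeq2. The fit with the lane term called 1 feature and none of these 4, with log2 fold changes of 1.36 for gene19551 (2.18 without the term), 1.36 for gene13883 (1.55), -2.23 for gene17606 (-2.58) and -2.57 for gene19494 (-2.45).

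At 4 months, gene600 had 34.9 ± 19.9 CPM in hawthorn against 6.89 ± 2.04 in apple (log2 fold change -2.34, SE 0.347, adjusted p = 0.000317, n = 5 each), and gene5798 had 4.25 ± 3.06 against 1.19 ± 0.328 CPM (adjusted p = 0.00373). Higher in apple were gene13545, with 4.14 ± 0.880 against 1.20 ± 0.844 CPM (log2 fold change 1.73, adjusted p = 0.00278), and gene16484, with 40.4 ± 17.9 against 13.2 ± 4.17 CPM (1.62, adjusted p = 0.0364). The call of gene16484 ended in 5 of the 10 fits without 1 of these libraries (adjusted p up to 0.111). This count rested on the 2 outlying hawthorn libraries: without both, 6 features were called, among them gene600 (-1.80) and gene5798 (-2.10, adjusted p = 0.0408 for each) but not gene13545 (1.30, 0.315) or gene16484 (1.82, 0.449). The count was 339 and 336 without hawthorn replicate 2 or 4 alone, and 3302 without hawthorn replicate 1, which lay at 27.3 on the first component. With the length slope as a term 3 features were called, and the fits with the lane term or with these 2 groups alone called 0 (1531 and 1499 at an unadjusted p under 0.05). The log2 fold changes of gene600, gene5798, gene13545 and gene16484 were -2.38, -1.86, 1.72 and 1.58 with the 2 groups alone (adjusted p = 0.349 for each) and -1.84, -1.69, 1.41 and 0.92 with the lane term (0.298, 0.361, 0.363 and 0.684).

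At 5 months, gene19551 stood at 7.28 ± 4.73 CPM in apple and 0.952 ± 0.454 CPM in hawthorn (log2 fold change 2.91, SE 0.528, adjusted p = 0.00118, n = 5 each). The abundant gene25032 had 345.7 ± 228 against 103 ± 26.8 CPM (1.74, adjusted p = 0.0139). Higher in hawthorn were gene27908, with 153 ± 29.3 against 45.1 ± 18.6 CPM (-1.76, adjusted p = 0.0195), and gene16789, with 7.04 ± 2.11 against 2.35 ± 0.660 CPM (-1.57, adjusted p = 0.00408). The length slopes of the 2 groups were -0.0179 in apple and 0.0921 in hawthorn (exact permutation p = 0.0397, adjusted p = 0.139 over 7 tests, n = 5). With the length slope as a term 362 features were called, without gene25032 (log2 fold change 1.11) and gene27908 (-1.01). The call of gene25032 also ended without apple replicate 1 (log2 fold change 1.28, adjusted p = 0.0686). That of gene27908 ended without apple replicate 3 or 4 or hawthorn replicate 3 (-1.70, -1.56 and -1.64, adjusted p up to 0.0777). With 1 library left out the count was between 279 (without apple replicate 4) and 1022 (without apple replicate 2), and it was 1855 without the 2 outlying hawthorn libraries. The lane term left 1 call, with log2 fold changes of 3.25 for gene19551 (adjusted p = 0.0887), 1.85 for gene25032 (0.296), -1.46 for gene27908 (0.449) and -1.88 for gene16789 (0.197).

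At 6 months, gene19551 had 7.81 ± 2.66 CPM in apple and 0.989 ± 0.645 CPM in hawthorn (log2 fold change 2.96, SE 0.521, adjusted p = 0.00443, n = 5 each), and gene13356 had 3.42 ± 1.36 against 1.16 ± 0.134 CPM (adjusted p = 0.0481). The very abundant gene23197 had 12510 ± 2715 CPM in hawthorn and 5628 ± 2699 CPM in apple (-1.15, SE 0.237, adjusted p = 0.0114), and gene7382 had 273 ± 63.01 against 97.5 ± 61.7 CPM (-1.49, adjusted p = 0.0481). Within lane 7, which held 4 apple and 3 hawthorn libraries of this month, 74 of the 75 features could be tested. All 74 kept their sign and 1, gene19551, was called. These libraries also gave the 75 calls, so the kept signs are not independent support. With the lane term 22 features were called, gene19551 (3.25, adjusted p = 0.0161) and gene23197 (-1.16, adjusted p = 0.0403) among them. The calls of gene13356 (log2 fold change 1.32 to 1.61) and gene7382 (-1.59 to -1.29) each ended in 8 of the 10 fits without 1 of these libraries (adjusted p up to 0.221 and 0.202). That of gene23197 ended without apple replicate 3 or 5 (-1.075 and -1.046, adjusted p = 0.0811 and 0.0975). With only these 2 groups fitted 5 features were called. The calls of gene13356 (1.56, adjusted p = 0.0609), gene7382 (-1.49, 0.135) and gene23197 (-1.15, 0.103) ended there. The count lay between 6 (without apple replicate 3) and 403 (without apple replicate 2), and was 0 without the 6 single-index libraries (452 at an unadjusted p under 0.05), which left 2 libraries per host. It was 323 without the 2 outlying hawthorn libraries (190 higher in apple, 133 lower), 307 with the length slope term (178 and 129) and 283 by DESeq2 (150 and 133).

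**Figure D3:**
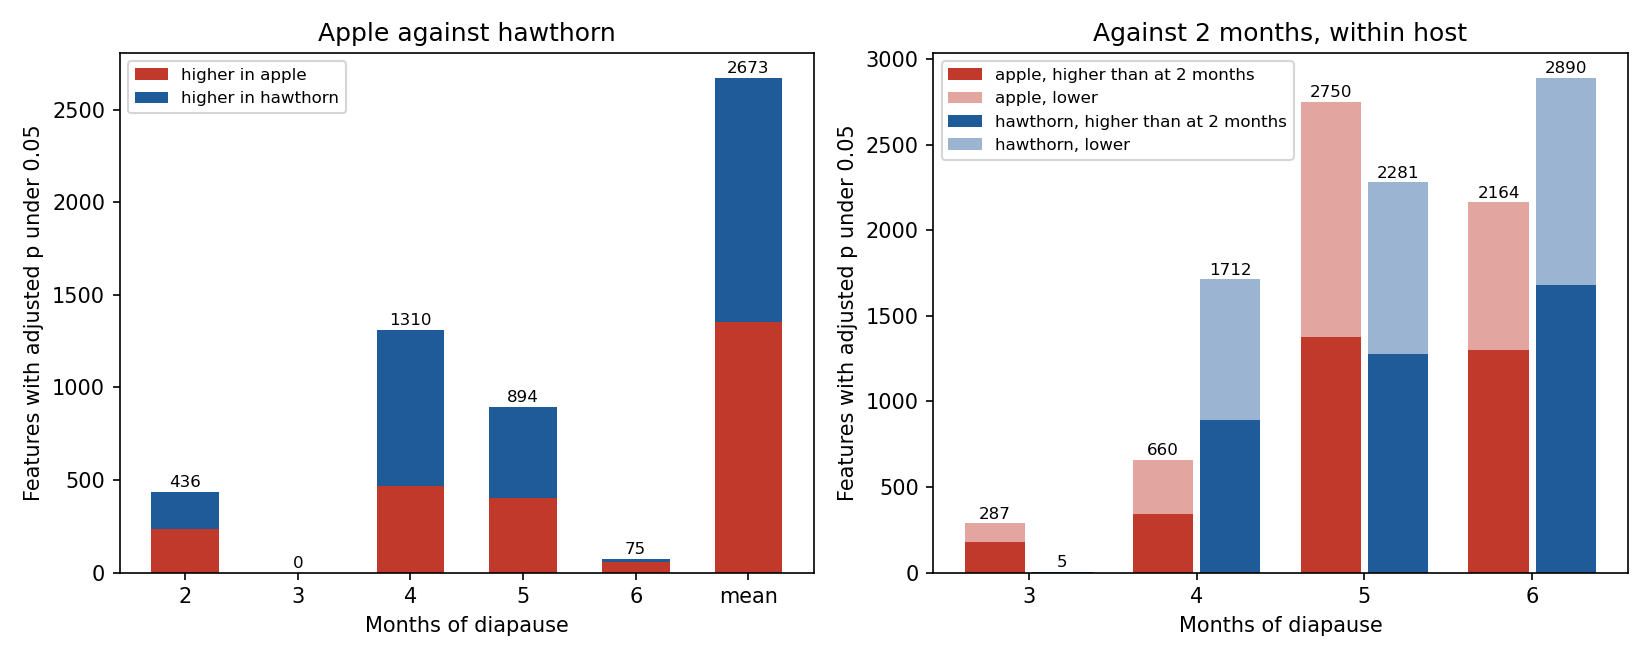
Number of features with an edgeR adjusted p under 0.05. Left, apple against hawthorn at each month and averaged over the 5 months, split by the host with the higher level; right, 3 to 6 months against 2 months within each host, split by direction. Host calls ran from 0 at 3 months to 1310 at 4 months. Calls against 2 months were highest at 5 months in apple (2750, and 2164 at 6 months) and at 6 months in hawthorn (2890).

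Across months, 2478 features were called between hosts in some month, 2253 of them in 1 month, 213 in 2 months, 12 in 3 months and 0 in 4 months. Of the features called in more than 1 month, 71 were called in both directions. These totals include the 1310 features of 4 months, a count that fell to 6 without the 2 outlying hawthorn libraries and to 3 with the length slope term. A direct test of the host-by-month interaction called 681 features, among them gene13883 (adjusted p = 0.0177), gene25032 (0.0324), gene7382 (0.0167) and gene23197 (0.0324). Of these, gene7382 was lower in apple at 6 months, while at 5 months apple libraries held 179 to 468 CPM and hawthorn libraries 125 to 180 CPM. For gene19551 the interaction was not called (adjusted p = 0.330). The interaction count was 2232 without hawthorn replicate 1 of 4 months, 161 without apple replicate 4 of 5 months, 190 with the length slope term, 214 without the single-index libraries and 0 with the lane term, and DESeq2 called 1640.

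The second question was how the CNS changed as diapause went on. In apple pupae 2811 features changed over the months (470 with the lane term and 4254 without the 2 outlying hawthorn libraries). Against 2 months, 287 differed at 3 months (178 higher, 109 lower), 660 at 4 months (344 and 316), 2750 at 5 months (1376 and 1374) and 2164 at 6 months (1299 and 865). From 2 to 6 months gene18780 rose from 16.6 ± 2.99 to 124 ± 59.0 CPM (log2 fold change 2.90, SE 0.358, adjusted p = 2.58e-07, n = 5 each). The less abundant gene16789 rose from 0.620 ± 0.264 to 4.32 ± 1.61 CPM (2.78, SE 0.356, adjusted p = 2.74e-07). Of the falling features, gene13519 went from 87.3 ± 60.2 to 7.71 ± 3.14 CPM (-3.48, SE 0.968, adjusted p = 0.0104) and gene20619 from 25.6 ± 10.2 to 4.37 ± 0.921 CPM (-2.54, SE 0.362, adjusted p = 2.21e-06). From 2 to 6 months 354 features were called with the lane term, among them gene18780 (adjusted p = 0.000918), gene16789 (0.00354) and gene20619 (0.00296) but not gene13519 (log2 fold change -4.30, adjusted p = 0.126), whose fold was larger than without the term. Without the single-index libraries 1054 features were called, and gene13519 lost its call (-3.12, adjusted p = 0.218). Apple libraries of 2 and 6 months shared no lane, so no comparison within a lane was possible. The 3-month count lay between 59 (without apple replicate 4 of 2 months) and 440 (without apple replicate 2 of 2 months) when 1 library was left out, and was 6 with the lane term. That term gave 18 features at 4 months and 432 at 5 months, and the 4-month count was 384 and 332 without replicates 4 and 5 of 2 months.

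In hawthorn pupae 5168 features changed over the months. With the length slope as a term the count was 2492, below that of apple (4111), and without the 2 outlying libraries it was 3527, also below that of apple (4254), so these data do not rank the hosts by it. Against 2 months, 5 differed at 3 months (2 higher, 3 lower), 1712 at 4 months (890 and 822), 2281 at 5 months (1275 and 1006) and 2890 at 6 months (1680 and 1210). From 2 to 6 months gene22517 rose from 0.935 ± 0.349 to 5.99 ± 3.31 CPM (log2 fold change 2.65, SE 0.484, adjusted p = 6.33e-05, n = 5 each) and gene9079 from 6.25 ± 3.27 to 32.3 ± 6.20 CPM (2.35, SE 0.281, adjusted p = 4.17e-08). The falling gene26176 went from 35.0 ± 27.8 to 3.36 ± 2.16 CPM (-3.37, SE 0.877, adjusted p = 0.00461), and gene13519, which also fell in apple, from 88.4 ± 73.5 to 9.32 ± 6.08 CPM (-3.24, SE 0.960, adjusted p = 0.0125). The length slope was -0.0560 at 2 months and 0.0678 at 6 months (exact permutation p = 0.0397, adjusted p = 0.139 over 7 tests, n = 5). With the length slope as a term 2797 features were called, 1884 of them among the 2890, and gene13519 lost its call (-2.54, adjusted p = 0.0675). With the lane term 2423 features were called, 2204 of them among the 2890, and gene13519 lost its call (-2.88, adjusted p = 0.0712). Without the single-index libraries 1305 were called, and gene26176 (-3.34, adjusted p = 0.132) and gene13519 (-3.05, 0.214) lost their calls. Within lane 7 alone, with 3 libraries of 6 months and 2 of 2 months, 758 features were called. Those of 6 months all carried a single index and those of 2 months a dual index, so index type changed with the month there. Of the 2823 testable features among the 2890, 99.8% kept their sign, but these libraries also gave the 2890 calls, so this is not independent support.

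At 3 months in hawthorn, the higher features were gene3366 (log2 fold change 1.13, SE 0.187, adjusted p = 0.00334) and gene8895 (0.78, SE 0.138, adjusted p = 0.00635), and the lower ones included gene23456 (-3.06, SE 0.605, adjusted p = 0.0261) and gene1392 (-2.07, SE 0.412, adjusted p = 0.0261). These identifiers were looked up after their values were seen. An unadjusted p under 0.05 was found for 1527 features at that month, DESeq2 called 60, and the edgeR count was 41 without hawthorn replicate 1 of 3 months. The edgeR count was 1 without replicate 2 of 3 months, 2 with the length slope term and 0 when only the 2 groups were fitted. In 8 of 100 splits of the month labels at least 5 features were called, so chance could not be excluded. At 5 months the count was 718 with the lane term (508 higher, 210 lower) and 1405 with the length slope term, 914 of them among the 2281. At 4 months it was 571 without the 2 outlying libraries, 1042 with the lane term, 2958 without replicate 1 of 4 months, and 0 when only the 2 groups were fitted.

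The third question was whether both hosts changed alike. From 2 to 6 months 1448 features changed in the same direction in both hosts, and these comparisons share no library. Of these, 954 were higher at 6 months in both, where independent lists would share 157, and 494 were lower in both, where 75.5 would be shared. Among the features called in apple 98.1% had the same sign in hawthorn, and among those called in hawthorn 97.2% had the same sign in apple. Over all tested features the share with the same sign was 77.1%. Across the 13862 features, which are not independent replicates, the fold changes of the 2 hosts had a Pearson correlation of 0.637 and a Spearman correlation of 0.687. The falling gene13519 was named by the rule in both hosts. A single feature, gene2300, was called in opposite directions, where 218 would be by chance. Its call in apple ended without replicate 2 of 2 months, which had 13651 counts against at most 27 in the other 4 libraries (log2 fold change from -7.10 to -0.34, adjusted p = 0.922). In hawthorn it ended without replicate 3 of 6 months, which had 3278 counts (from 6.98 to 1.74, adjusted p = 0.610). A direct test of the host difference in the change from 2 to 6 months with edgeR called 0 features; 632 had an unadjusted p under 0.05, DESeq2 called 2, and the smallest adjusted p was 0.0558. In both hosts replicates 3, 4 and 5 of 6 months carried a single index and all libraries of 2 months a dual index. The shared count was 613 without the single-index libraries and 318 with the lane term.

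**Figure D4:**
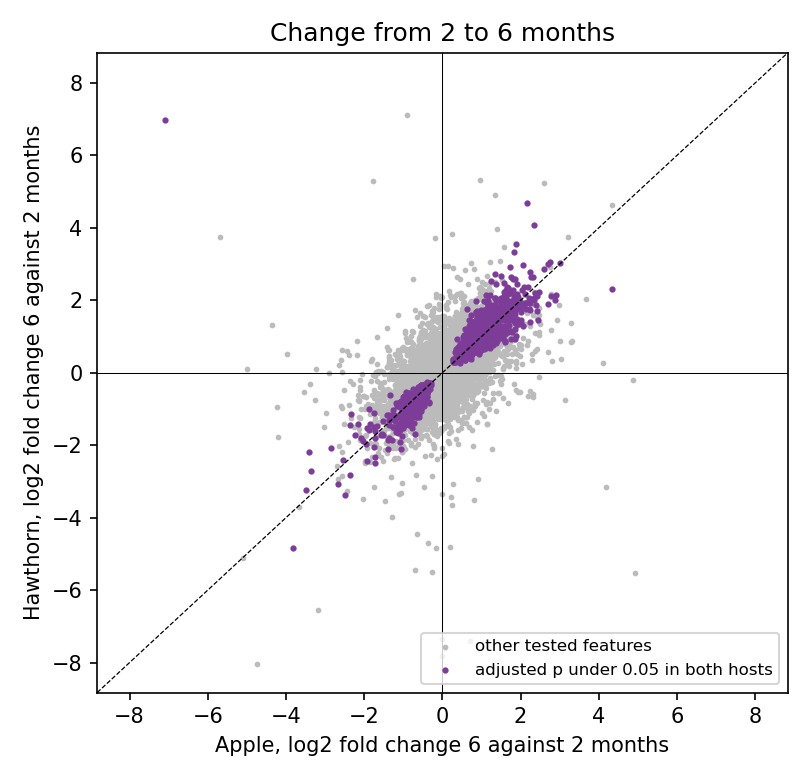
Log2 fold change from 2 to 6 months in apple (horizontal) against hawthorn (vertical) for the 13862 tested features. Purple points had an edgeR adjusted p under 0.05 in both hosts (954 higher and 494 lower at 6 months in both, and 1 opposite), and the dashed line marks equal change.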

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

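The test of sequencing depth in the outlying libraries was chosen after their totals were seen, and the length slope term, its test on the change from 2 to 6 months and the loss of the 2 outlying libraries were added after seeing the data; the tests of lanes, of transcript length in the outlying libraries, of mislabelling and of other splits were set out before their results were seen.

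In 60 checks of library measures within groups of 5, 5 values, from 4 libraries, stood apart from those of the other 4 libraries of their group, where chance gives about 3. A value stood apart if its gap to the nearest value exceeded 0.71 of the group's range (Dixon's ratio). The number by chance assumes normally distributed values, which was not checked. Apple replicate 2 of 6 months had 24840142 expected counts (others 10848487 to 12900759). Hawthorn replicate 5 of 5 months had 15917 detected features (others 17029 to 17282). Apple replicate 4 of 4 months had a TMM factor of 1.05 (others 1.11 to 1.14). Hawthorn replicate 5 of 6 months had a length slope of -0.0770 (others 0.0999 to 0.110) and lay at -5.47 on the first component (others 24.3 to 34.4). Apple replicate 2 of 6 months correlated better with the hawthorn mean of 6 months (0.985) than with its own group mean (0.976). Hawthorn replicate 5 of 6 months did so with the apple mean of 6 months (0.976 against 0.973). Other libraries also correlated best with another group, such as hawthorn replicate 2 of 2 months with apple at 3 months (0.981 against 0.977). A swapped label was not tested for these libraries.

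In 80 checks of named features by the same ratio, 15 values stood apart, where chance gives about 4. That number also assumes normally distributed values, which was not checked for CPM, so the excess may come from their distribution. For gene14752 there were 7 of them: 40.1 CPM in apple replicate 5 of 3 months, 3.41 in apple replicate 2 of 4 months, 5.57 in apple replicate 4 of 5 months, 9.25 in hawthorn replicate 4 of 2 months, 102 in hawthorn replicate 4 of 4 months, 24.9 in hawthorn replicate 5 of 5 months and 65.0 in hawthorn replicate 1 of 6 months, while no other library of those groups exceeded 5.93 CPM. For gene19551 the hawthorn libraries apart were replicate 4 of 3 months (2.98 CPM, others up to 1.55) and replicate 5 of 5 months (0.152 CPM, others from 1.05). Hawthorn replicate 5 of 5 months also held 6.98 CPM of gene17606 (others up to 1.26), and replicate 5 of 6 months 17360 CPM of gene23197 (others up to 11440). Apple replicate 5 of 2 months had 0.152 CPM of gene16789 (others from 0.692), apple replicate 2 of 6 months 13.2 CPM of gene13519 (others up to 6.88) and apple replicate 2 of 4 months 5.66 CPM of gene13545 (others up to 4.01). Hawthorn replicate 5 of 2 months had 83.1 CPM of gene26176 (others up to 34.0).

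The host difference changed with the month by a direct edgeR test in 681 features, and among the named ones in gene13883 (adjusted p = 0.0177), gene25032 (0.0324), gene7382 (0.0167) and gene23197 (0.0324). The count depended on the fit: it was 0 with the lane term, 190 with the length slope term and 161 to 2232 with 1 library left out.

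The mean host difference was 2673 features, and 21 with lane as a term. Lanes shuffled within groups overlap the groups as the real lanes do but carry no lane information. In 100 shuffles they gave counts from 2 to 1296 with a median of 62, so 21 lies within what a term of this shape gives by itself. On simulated counts the fit with the term recovered 59 of 100 changes of 1.5-fold and 89 of 100 of 2-fold. Their median absolute log2 fold changes were 0.63 and 1.01, against 0.35 for the 2673 features. These shares therefore do not tell how many of the 2673 calls the term should keep. Over the 2673 features the median SE rose from 0.0932 to 0.167 and the median signed log2 fold change went from 0.35 to 0.31, where a lane effect as the whole cause would have brought it to about 0, but single features also lost part of their fold (gene17606 from -1.30 to -0.70, gene14752 from -1.62 to -0.68). The length slope term gave 3544 features and the loss of the 2 outlying libraries 3181, which argues against either as the cause. A partial contribution of lanes stays open, and a difference between the hosts' pupae is a hypothesis that these data do not separate from the handling of the 2 fruit types.

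Hawthorn replicates 2 and 4 of 4 months stood apart on the first component. Low depth is argued against as the cause in both, since replicate 2 had 17111389 counts against a median of 14615586 in the other 48 libraries, and replicate 4 had 11161517, more than replicate 5 of that group (8718271), which lay at -5.30 on the first component. For a swapped label within the study, the highest correlation of either with any group mean was 0.941, below the lowest own-group correlation of the other 48 (0.951). A strong length trend would lower the correlation with every group mean whatever the label, so this test cannot decide on a swap. Their length slopes of -0.270 and -0.272 lay outside the range of the others (-0.133 to 0.157), so a candidate explanation is a loss of long transcripts, as RNA breakdown or a library step could give. No biological explanation was tested for these 2 libraries.

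The change from 2 to 6 months was large in both hosts (2164 features in apple, 2890 in hawthorn), while months were spread unevenly over lanes. With the lane term 354 and 2423 features were called, and in hawthorn 758 were called within lane 7 alone. In that lane the hawthorn libraries of 6 months all carried a single index and those of 2 months a dual index. The fit within lane 7 therefore does not separate months from index type. Shuffled lanes gave 227 to 1242 in apple (median 559, 9 of 100 at or below 354). In hawthorn they gave 1750 to 3893 (median 2234.5, 67 of 100 at or below 2423). The apple count thus lay near the low end of its range, and a part of lanes stays open there. The median signed log2 fold changes of the called features went from 0.82 to 0.73 in apple and from 0.85 to 0.90 in hawthorn with the lane term, so lanes as the whole cause are argued against. The length slope term gave 2846 and 2797 features, with median signed log2 fold changes of 0.79 and 0.73, which argues against the trend with transcript length as the whole cause, although 1884 of the 2890 hawthorn features were still called and a part stays open. Months of diapause may be the cause, but each month was also dissected at its own time, which cannot be separated here.

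Other splits of the samples were drawn 100 times, the real one included. Each split changed the labels of all months at once, so real differences at other months added to its spread. A small count in the splits therefore does not test a single comparison by itself. For the host difference at 2 months (436, highest other 2) and 5 months (894, highest other 590) only 1 split, the real one, was as large. The same held for the mean (2673, 1 as large, highest other 354), where the splits argue against random host labels over the months as a whole. At 6 months (75, highest other 155) 3 splits were as large, under the limit of 5 set in advance. The comparisons were not adjusted for their number, and 1 in 100 is the smallest share these splits can give. Chance is therefore not excluded for the host difference at any single month. For the interaction (681, 1 as large, highest other 199) the splits also broke up the mean host difference. They therefore do not test chance for the interaction alone. At 4 months 2 of 100 splits were as large (1310, highest other 1797), so chance is not excluded there either. The count may also come from the 2 outlying hawthorn libraries, without which 6 features were called. For the host difference at 3 months (0, highest other 2) and the difference in change from 2 to 6 months (0, highest other 361) all 100 splits were as large as a count of 0 by construction, so the splits say nothing about chance there. In apple 1 split of 100 was as large for 3 months (287, highest other 3), 4 months (660, highest other 2), 5 months (2750, highest other 2), 6 months (2164, highest other 93) and any change (2811, highest other 11). This excludes a random order of the months as a whole. In hawthorn 1 split of 100 was also as large for 4 months (1712, highest other 147), 5 months (2281, highest other 1930), 6 months (2890, highest other 673) and any change (5168, highest other 1285). The 4-month count was 571 without the 2 outlying libraries and 0 when only the 2 groups were fitted. At 3 months 8 of 100 splits gave at least the 5 called features (highest other 526), so chance could not be excluded there.

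Splits that called many features point to a structure of the samples. At 4 months 44 of the other splits put hawthorn replicates 2 and 4 in the same group, the split with 1797 calls among them, and the highest edgeR count of the splits that parted these 2 libraries was 0. For the hawthorn changes to 3, 5 and 6 months the highest other splits also had both libraries in 1 group, and those without both in 1 group reached 161, 1002 and 210. The structure behind the 361 calls for the difference in change was not tested.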

How the results depend on the processing

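Leaving out the 2 outlying hawthorn libraries, the length slope term and the hawthorn fits within lanes were chosen after seeing the data. With 5 libraries per group, few simulated changes of 1.5-fold were recovered, and the role of depth was not tested. Lower counts under a stricter threshold follow from that choice, and for the other settings the cause was not tested. Without the 2 outlying libraries, counts also rose in comparisons that hold no hawthorn library of 4 months. The apple change to 3 months went from 287 to 549 and the host count at 6 months from 75 to 323. All groups share 1 estimate of the spread, so these 2 libraries can lower counts of comparisons they are not part of. Leaving out the single-index libraries changed index type and library number at once. DESeq2 size factors moved no count by over 1.5 times. The mean host difference (2673) stayed within 1.5 times of its value except with the lane term (21), at an adjusted p under 0.01 and without the single-index libraries, and the hawthorn change from 2 to 6 months (2890) except for these last 2 settings and lane 7. Without the low-count filter host counts were 276 at 2, 833 at 4, 544 at 5 and 42 at 6 months, the apple change to 3 months 154 and the interaction 339. The lane term gave host counts of 1 at 2, 0 at 3, 0 at 4, 1 at 5 and 22 at 6 months (584 and 1531 features had an unadjusted edgeR p under 0.05 at 3 and 4 months). It also gave apple changes of 6, 18, 432 and 354 at 3 to 6 months, hawthorn changes of 11, 1042 and 718 at 3 to 5 months, 470 features changing over months in apple and 3409 in hawthorn, 318 shared changes and 0 interactions (1753 at an unadjusted p under 0.05). Without the single-index libraries the host count was 0 at 6 months (452 at an unadjusted edgeR p under 0.05) and 1399 for the mean, apple 1054 at 6 months, hawthorn 3 at 3 and 1305 at 6 months, apple over months 1867, the interaction 214 and the shared change 613. With edgeR 4's bias-adjusted deviances the host count at 3 months was 1. Without the 2 outlying hawthorn libraries host counts were 1196, 9, 6, 1855 and 323 at 2 to 6 months, apple changes 549 and 1036 and hawthorn changes 38 and 571 at 3 and 4 months, and apple over months 4254. The length slope term gave host counts of 1079, 19, 3, 362 and 307 at 2 to 6 months, apple changes of 521 and 1000 at 3 and 4 months, hawthorn changes of 2 and 1405 at 3 and 5 months, hawthorn over months 2492 and the interaction 190. At an adjusted p under 0.01 host counts were 58 at 2, 348 at 4, 163 at 5 and 11 at 6 months and 1343 for the mean, apple changes 56, 253, 1461 and 1147 and hawthorn changes 2, 636, 1085 and 1651 at 3 to 6 months, 1487 and 3006 over months, and the interaction 40. Fitting only the 2 groups compared gave host counts of 1080 at 2, 3 at 3, 0 at 4 and 5 at 6 months, and hawthorn changes of 0 at 3 and at 4 months (1499, 1831 and 1810 at an unadjusted edgeR p under 0.05 for the 3 zeros). DESeq2 called 780 at 2, 35 at 3 and 283 at 6 months between hosts (150 higher in apple and 133 lower, against 55 and 20), apple 484 and hawthorn 60 at 3 months, 2 for the difference in change and 1640 interactions. Within lane 7 the host count at 6 months was 1 and the hawthorn change to 6 months 758, and within lane 1 the hawthorn counts were 4 at 3 months and 0 at 4 months (613 at an unadjusted edgeR p under 0.05). With the replicate number as a block the mean host difference was 2638, and no count moved by over 1.5 times. These numbers do not pair the samples, since same-number libraries of different groups had a mean residual correlation of 0.0164 (from -0.308 to 0.331). Without any 1 library, counts stayed within 1.5 times for the mean host difference (2364 to 3096), apple at 5 and 6 months (1993 to 2670, 1582 to 2082), hawthorn at 5 and 6 months (1644 to 2190, 2287 to 2965), apple and hawthorn over months (2191 to 2858, 4205 to 6342) and the shared change (1139 to 1423). The host count at 2 months ranged from 98 to 632, with 273, 224, 98 and 108 without apple replicates 1, 3, 4 and 5 and 168, 152 and 279 without hawthorn replicates 1, 4 and 5. At 3 months it ranged from 0 to 8, with 2, 2, 3 and 2 without apple replicates 1, 2, 3 and 5 and 8 without hawthorn replicate 1. At 4 months (336 to 3302) it was 745, 780 and 725 without apple replicates 1, 2 and 3, and 3302, 339 and 336 without hawthorn replicates 1, 2 and 4. At 5 months (279 to 1022) it was 577, 437 and 279 without apple replicates 1, 3 and 4, and 552, 388, 447 and 518 without hawthorn replicates 1, 3, 4 and 5. At 6 months (6 to 403) it was 403, 6 and 10 without apple replicates 2, 3 and 5, and 23, 33, 14 and 38 without hawthorn replicates 1, 2, 3 and 4. The apple change to 3 months (59 to 440) was 164, 440, 59 and 61 without replicates 1, 2, 4 and 5 of 2 months and 166, 150, 126 and 115 without replicates 1, 2, 3 and 5 of 3 months, and that to 4 months (332 to 706) 384 and 332 without replicates 4 and 5 of 2 months. The hawthorn change to 3 months (1 to 41) was 11, 14 and 2 without replicates 1, 2 and 4 of 2 months and 41, 1, 2, 2 and 3 without replicates 1 to 5 of 3 months, and that to 4 months (914 to 2958) 2958, 1028 and 914 without replicates 1, 2 and 4 of 4 months. The difference in change was 0 or 1, with 1 without apple replicates 1, 3, 4 or 5 of 2 months or hawthorn replicates 1, 2, 4 or 5 of 6 months. The interaction (161 to 2232) was 452 without apple replicate 5 of 2 months, 260, 347, 331 and 394 without apple replicates 1 to 4 of 4 months, 224, 396 and 161 without apple replicates 1, 3 and 4 of 5 months, 2232, 434, 410 and 1117 without hawthorn replicates 1, 2, 4 and 5 of 4 months, and 272, 201 and 246 without hawthorn replicates 1, 3 and 4 of 5 months. Of 28 tests of named features, calls were held in 28 with DESeq2 and with the block, 27 with edgeR 4's deviances, 26 with DESeq2 size factors, 25 without the filter, 25 without the outlying libraries, 22 with the length slope, 20 without single-index libraries, 19 at an adjusted p under 0.01, 9 with the lane term, 17 of 24 in fits of 2 groups and 5 of 8 within lane 7 (1 of 4 between hosts, 4 of 4 in the hawthorn change). Without 1 library 413 of 440 were held. The other 27 were 8 each for gene13356 and gene7382 at 6 months, 5 for gene16484 at 4 months, 3 for gene27908 and 1 for gene25032 at 5 months and 2 for gene23197 at 6 months. No direction reversed in any of these settings. The rule that named these features asked for group values that did not overlap, or for the same sign at all 5 months. Kept directions were thus largely fixed by that choice and are not support.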

Other observations

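The abundant features, gene2300 and the 32-fold count were chosen after their values were seen, while the tests of progress through diapause and of neighbouring feature numbers were set out before their results were seen.

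Among the most abundant features, gene2503 fell from 2.25 ± 0.264% of the counts at 2 months to 1.37 ± 0.189% at 6 months in apple (n = 5 each, edgeR adjusted p = 0.0117) and from 2.87 ± 0.275% to 1.33 ± 0.247% in hawthorn (adjusted p = 3.14e-05). Another abundant feature, gene15755, was lower in apple than in hawthorn over the 5 months (log2 fold change -0.29, SE 0.0555, adjusted p = 0.000253).

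A few libraries held very high levels of single features. In 4 libraries gene2300 had 2506 to 13651 counts (189.3 to 408.5 CPM), and in the other 46 at most 38 counts (2.66 CPM). Of 13862 tested features, 44 exceeded their own median 32-fold in some library, 25 of them in 1 library and none in more than 7. Such values occurred in 35 libraries, with the most, 10 features, in apple replicate 5 of 5 months.

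The hypothesis that apple pupae were further along than hawthorn pupae in the change both hosts shared was examined with a score over the 1448 shared features, set to 0 at 2 months and 1 at 6 months in each host. At 3 months the score was 0.418 ± 0.0867 in apple and 0.356 ± 0.0731 in hawthorn (n = 5, exact permutation p = 0.238, adjusted p = 0.357 over 3 tests). At 4 months it was 0.630 ± 0.0627 and 0.481 ± 0.0958 (exact permutation p = 0.0238, adjusted p = 0.0714), and at 5 months 0.812 ± 0.142 and 0.824 ± 0.0684 (exact permutation p = 0.881, adjusted p = 0.881). Without the 2 outlying libraries the hawthorn score at 4 months was 0.518 ± 0.102 (n = 3, exact permutation p = 0.107). The score did not differ past the threshold at any of the 3 months. Because its ends were set within each host, it compares only the course between them and cannot show a lead that apple kept from 2 to 6 months, so the hypothesis stays open.

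The hypothesis that features differing between hosts lie in runs of neighbouring feature numbers was tested on 8904 pairs of tested features with consecutive numbers. Both were called in the mean host difference in 368 pairs, where the central range of 1000 reorderings, without its extremes, was 302 to 364. Of these pairs 63.9% differed in the same direction, where the central range was 44.4 to 55.3%. The test was positive. What the numbering follows is not known, so whether such features lie side by side on a chromosome was not tested.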
